A study of Ciona robusta with 133 samples.

How the data were processed

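Gene expression was measured in single blastomeres that were dissected by hand from embryos of the ascidian Ciona robusta, at the 16-, 32-, 64- and 112-cell stages and at the 6-row neural plate stage. Cell types carry Conklin names, in which A cells belong to the anterior vegetal lineage and a cells to the anterior animal lineage. The 133 libraries cover 19 cell types at 5 stages, with 72 libraries of A cells and 61 of a cells. Per the labels' protocols, cDNA was amplified from single cells with a low-input template-switching kit, libraries were made by tagmentation, and single-end reads came from a NextSeq instrument. The neural plate labels name 2 cells per group, such as A9.13+A9.14, while the protocol speaks of an isolated cell, and the labels do not say which of the named cells a library holds.

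The authors deposited a table of whole-number read counts per gene, without normalization, for 15287 gene models with KH identifiers. Reads were aligned with STAR 2.7.10a, per the submitters' processing notes; the genome build, the gene annotation and the counting program are not given in the sources used here. Whether the counts kept strand, and how reads shared by near-identical genes were assigned, is not given either, so paralogs and overlapping genes are uncertain. The reads carry no molecular identifiers, so counts are PCR-amplified reads and not molecules, and all counting intervals and limits below cover counting error only. The counts in the deposited table were used as they stand, and 244 gene models had no count in any library. All columns were matched to a sample by name, and 0 columns were left unmatched. Total counts ranged from 1452103 to 16599891 per library, with a median of 7546701.

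The labels name the embryo and the side of every cell. Cells of 1 type from 1 embryo are not independent, so their counts were summed, which gave 87 embryo samples, and n below counts embryos. The A9.13+A9.14 group has 2 embryos, and the other groups have 3 to 8. No libraries of a group agreed within sampling noise (the lowest chi-square per gene between libraries of a group was 13.03), so none was treated as a duplicate.

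Groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust dispersion) after TMM normalization and edgeR's own filter on low counts by group. All cell types of a stage shared 1 fit, and the steps between successive stages were fitted per lineage. P-values were adjusted with the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 are counted as higher or lower. Every adjusted p below comes from this test unless another is named, and standard errors (SE) of log2 fold changes were taken from its F statistic. Levels are CPM (read counts divided by the TMM-scaled total of the sample), given as mean ± SD over embryos. CPM in comparisons of stages were scaled within the lineage, and therefore differ slightly from those within a stage.

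A-line and a-line neural-side cells were compared at each stage, and each was compared with the partner cell type collected from the same lineage. The lineage difference is the A-line log2 change from partner to neural side minus the a-line change, tested in the same fit. Shared changes are genes past the threshold in the same direction in both lineages, set against the number expected from independent lists and tested with one-sided Fisher's exact tests. The distance between cell types is the mean over genes of the squared difference in log2 CPM (prior count 2) after the sampling part was subtracted, so it can fall below 0. Its SE comes from a jackknife over embryos. For partners, the distance was taken from products of differences in separate embryos, a choice made after the data were seen, and it is given for A5.1 and a5.3 beside the unpaired value.

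The labels state that partner cells share embryos, and likewise A5.1 and a5.3, so these comparisons are paired. Residual log2 expression of libraries from the same embryo correlated with a mean r of 0.358 between A5.1 and a5.3, and within a lineage with 0.374 at 32 cells, 0.138 at 64 cells, 0.0324 at 112 cells and 0.0177 at the neural plate stage. A fit with the embryo as a block (replicate block) was an alternative to the unblocked fit, and its values are given where they differ. Equal embryo numbers in A-line and a-line cells at 32, 64 and 112 cells are not stated to mark the same embryo, and the mean r there was 0.00717, -0.0122 and 0.00841.

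The rule for named genes was fixed before the data were examined. It takes genes past the threshold with a mean of at least 5 CPM in the higher group and every embryo of that group above every embryo of the other, ranked by absolute log2 fold change. The files do not pair the KH identifiers with gene names, and 0 of them were in the reference table, so at most 2 identifiers per direction are printed for a comparison. Fixed lists of lineage regulators, signalling genes and markers of other cell types could not be applied for the same reason. The identifiers of the genes changed in both lineages were chosen after their values were seen. A fold against a group without any count is a lower limit, computed from pooled counts against 3 counts over that group. With 1 to 3 counts, the ratio of pooled counts is given with its exact 95% counting interval.

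Alternatives were RLE size factors, no low-count filter, a stricter filter (10 CPM), single libraries as replicates, fits of only the 2 groups compared, the embryo block, DESeq2 1.42.0 and limma 3.58.1 voom with an estimated embryo correlation. Further fits left out each embryo of the groups compared in turn. A fit without 1 A6.1 library that stood apart was added after the data were seen. Figures were drawn with matplotlib 3.10.9.

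The tests were tested on simulated counts with the real means, library sizes and numbers of embryos, in which 100 genes changed 4-fold and 100 changed 2-fold. Of the 4-fold changes, 90% were called in A5.1 against a5.3, 44% in A6.2 against a6.5 and 86% in A7.4 against a7.10. The share was 75% in A8.7 against a8.19 and 31% in A9.13+A9.14 against a9.37+a9.38. For partners, the share of 4-fold changes called was 59% in A6.2 against A6.1, 26% in a6.5 against a6.6, 72% in A7.4 against A7.3, 84% in a7.10 against a7.11, 61% in A8.7 against A8.5, 63% in a8.19 against a8.22, 40% in A9.13+A9.14 against A9.9+A9.10 and 34% in a9.37+a9.38 against a9.43+a9.44. The 2-fold changes were called in 79% of genes in A5.1 against a5.3, in 6% in A6.2 against a6.5 and in 0% in A9.13+A9.14 against a9.37+a9.38. These comparisons, simulated on 9935 to 11826 genes, made 0 to 6 false calls each. The properties taken from the data did not include the correlation between cells of the same embryo or a library that stands apart. For A6.2 against A6.1 the simulation made 2 false calls. The real fit called 1556 genes there, and 0 without the A6.1 library that stood apart. The simulated shares and false calls may therefore not hold for paired cells or for fits that include that library.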

Results

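Single cells of 2 lineages that both contribute to the ascidian nervous system were profiled in Ciona robusta, a tunicate whose early cell divisions follow an invariant pattern. The series title asks how similar these lineages are early in development. The neural side of the A line ran from A5.1 through A6.2, A7.4 and A8.7 to A9.13+A9.14. The neural side of the a line ran from a5.3 through a6.5, a7.10 and a8.19 to a9.37+a9.38. Partner cells of the same lineage were A6.1, A7.3 with A7.2, A8.5 and A9.9+A9.10 on the A side, and a6.6, a7.11, a8.22 and a9.43+a9.44 on the a side. By textbook fate maps, A7.3 and its descendants A8.5 and A9.9+A9.10 form notochord, and a7.11, a8.22 and a9.43+a9.44 form epidermis.

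Each of the 19 cell types was represented by 6 to 9 libraries from 2 to 8 embryos. The total count per library ranged from 1452103 to 16599891, with a median of 7546701. The number of genes with at least 1 count had a median of 10745 per library. By cell type it was highest in a5.3, a6.5, a6.6 and A5.1, with medians of 11483, 11475, 11441 and 11417, and lowest in A8.5, with a median of 10003. One A6.1 library, from the left side of embryo 5, had 7137 genes, against 9667 or more in every other library. Its median correlation with the other A6.1 libraries was 0.286, against 0.917 to 0.937 for those libraries. Results at the 32-cell stage are therefore also given without it.

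**Figure D1:**
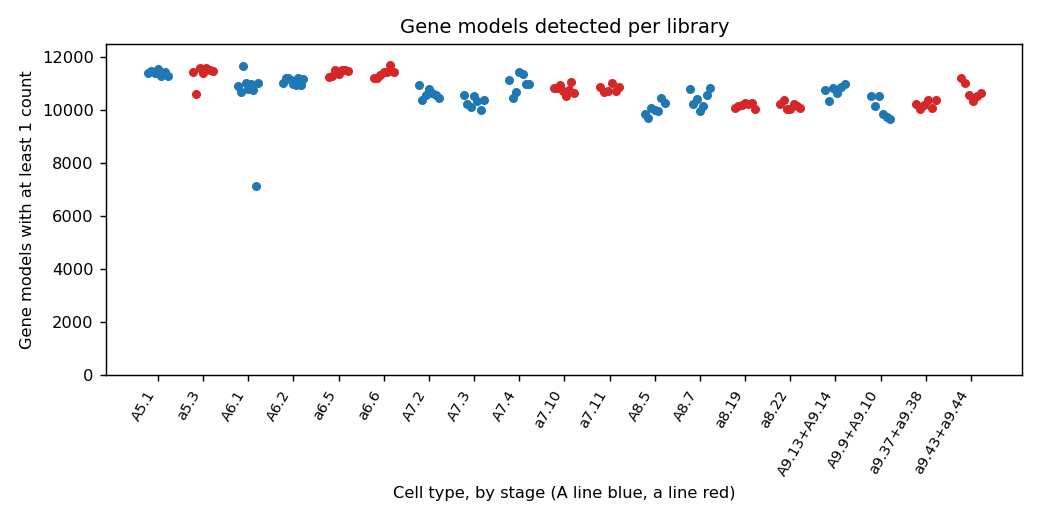
Genes with at least 1 count in each library (points, 1 per library) on the y axis, by cell type along the x axis in order of stage, with A-line cells in blue and a-line cells in red. The lone low point, at 7137 genes, is the A6.1 library of embryo 5.

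The transcriptomes of the A-line and a-line neural-side cells lay farther apart from the 32-cell stage on than at the 16-cell stage. Their distance, the mean squared log2 difference over genes, was 0.0310 ± 0.0522 (jackknife SE, n = 5 embryos each) between A5.1 and a5.3, and 0.0768 ± 0.00683 when taken within the 5 embryos they share. It was 0.574 ± 0.09997 between A6.2 and a6.5 (n = 6 and 5), 0.820 ± 0.171 between A7.4 and a7.10 (n = 4 and 8) and 0.660 ± 0.209 between A8.7 and a8.19 (n = 5 and 4). At the neural plate stage A9.13+A9.14 and a9.37+a9.38 lay 0.505 apart, with no SE because A9.13+A9.14 came from 2 embryos. Neural-side and partner cells of the same lineage were much closer to each other at first. For the a line, their within-embryo distance rose from 0.124 ± 0.0194 between a6.5 and a6.6 (n = 5) to 0.179 ± 0.0356 between a7.10 and a7.11 (n = 6), 0.475 ± 0.0749 between a8.19 and a8.22 (n = 4) and 0.770 ± 0.108 between a9.37+a9.38 and a9.43+a9.44 (n = 3). In the A line it was 0.142 ± 0.0725 between A7.4 and A7.3 (n = 4), 0.381 ± 0.106 between A8.7 and A8.5 (n = 5) and 0.458 between A9.13+A9.14 and A9.9+A9.10 (n = 2, no SE). For A6.2 and A6.1 it was 0.136 ± 0.0894 (n = 6), and 0.0603 ± 0.0330 without embryo 5. The neural-side cells of the 2 lineages were farther from each other than from their own partners at 3 stages, by more than the SE at 32 and 64 cells and by less in the a line at 112 cells. At the neural plate stage a9.37+a9.38 lay closer to A9.13+A9.14 than to its own partner, a difference that could not be tested. It lay as close to the notochord-fated A9.9+A9.10 (0.5025 ± 0.247, n = 3 each), so this closeness was not particular to the neural sides. The distance of A9.13+A9.14 to its own partner was 0.458 within embryos and 0.590 unpaired, on either side of 0.505. From 64 to 112 cells and on to the neural plate stage, the change in the distance between lineages was within its SE or had none. A5.1 and a5.3 shared embryos, while A-line and a-line cells of later stages were not shown to. A collection difference between the lineages would therefore add to their distances from 32 cells on. It would not add to the distance at 16 cells or to partner distances within embryos. How much it added cannot be told from these samples.

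**Figure D2:**
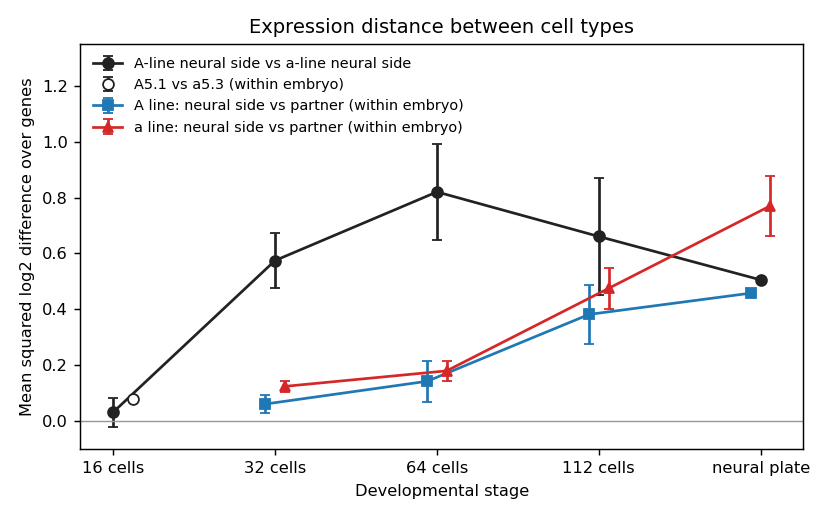
Mean squared log2 difference over genes (y axis) between cell types at each stage (x axis), for A-line against a-line neural-side cells and for neural-side against partner cells of each lineage within embryos. Bars are jackknife SE over embryos, absent where a group has 2 embryos, and the A-line partner value at 32 cells leaves out embryo 5. The open circle is the distance of A5.1 and a5.3 within embryos. The distance between lineages rises from 0.0310 (0.0768 within embryos) at 16 cells to 0.820 at 64 cells, while the mean partner distances are higher at each later stage. From 32 cells on the lineages were not shown to share embryos, so their distance can include a collection difference.

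At the 16-cell stage A5.1 and a5.3 differed in 15 genes of 9935 tested, of which 3 were higher in A5.1 and 12 in a5.3. KH.C2.125 stood at 49.5 ± 22.9 CPM in A5.1 and 2.17 ± 1.36 CPM in a5.3 (SD, n = 5 each; log2 fold change 4.56 ± 0.48 SE, adjusted p = 0.00154). KH.C11.577 was also higher in A5.1, at 7.04 ± 4.54 against 0.428 ± 0.286 CPM (adjusted p = 0.0487). KH.C9.541 was higher in a5.3, at 10.4 ± 6.08 against 0.146 ± 0.326 CPM (adjusted p = 0.0443), and so was KH.S545.6, at 79.3 ± 21.4 against 30.1 ± 5.48 CPM (adjusted p = 0.0109). In a fit with the embryo as a block 128 genes passed, 23 higher in A5.1 and 105 higher in a5.3, including all 15. Fits without 1 embryo gave 2 genes (without A5.1 embryo 4) to 24 genes (without A5.1 embryo 5). Of these 10 fits, KH.C9.541 and KH.C11.577 each lost the call in 8 and KH.S545.6 in 4, and without the low-count filter 5 genes passed, 1 higher in A5.1 and 4 in a5.3.

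At the 32-cell stage the A-line neural-side cell A6.2 and the a-line neural-side cell a6.5 differed in 53 of 11237 genes, 12 higher in A6.2 and 41 higher in a6.5. KH.C12.14 was higher in A6.2, at 14.99 ± 7.09 CPM (n = 6) against 0.192 ± 0.264 CPM in a6.5 (n = 5; adjusted p = 0.00557). KH.C10.322 stood at 81.6 ± 22.2 CPM in A6.2 and 5.29 ± 2.80 CPM in a6.5 (log2 fold change 3.94 ± 0.74 SE, adjusted p = 0.0125). KH.S1904.1 had no count in any A6.2 embryo and 20.1 ± 12.8 CPM in a6.5, so it was at least 468-fold higher there (adjusted p = 3.1e-05). KH.C9.218 had 2 counts in A6.2 and 12.9 ± 7.61 CPM in a6.5, a ratio of 412 with a counting interval of 114 to 3411 (adjusted p = 0.000182). The count was 1135 genes, 567 higher in A6.2 and 568 in a6.5, and included all 53, when the A6.1 library that stood apart was left out of the shared fit. With RLE size factors 225 genes passed, 76 higher in A6.2 and 149 in a6.5. Fits without 1 embryo of A6.2 or a6.5 gave 25 genes (without A6.2 embryo 1) to 42 genes (without A6.2 embryo 3).

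For the A line at the 32-cell stage, the calls between A6.2 and A6.1 rested on 1 library. In all embryos 1556 genes passed, 22 higher in A6.2 and 1534 higher in A6.1, and without the A6.1 library of embryo 5 the count was 0. That library had a TMM factor of 0.0375, against 1.13 to 1.20 in the other 32-cell samples, which raises its CPM. Of the 1534 genes, 1290 also stood above the A6.2 mean in it without this scaling, and 1116 had a mean of the other A6.1 embryos above the A6.2 mean. KH.C5.217 stood at 99090 CPM (3712 without the scaling) in A6.1 of embryo 5 and at 69.8 to 84.8 CPM in A6.1 of the other 5 embryos, against 62.5 ± 3.79 CPM in A6.2 (n = 6; adjusted p = 0.0119 with all embryos and 0.9999 without A6.1 of embryo 5). KH.S215.4 stood at 52230 CPM (1957 without the scaling) in A6.1 of embryo 5 and at 18.4 to 54.0 CPM in the others, against 6.33 ± 3.15 CPM in A6.2 (adjusted p = 0.0119, and 0.116 without A6.1 of embryo 5). With the embryo as a block 4 genes passed, 3 higher in A6.2 and 1 higher in A6.1, and the adjusted p of KH.C5.217 and KH.S215.4 was 0.909. By edgeR, 2058 genes had an unadjusted p below 0.05 with all embryos; DESeq2 called 21 genes and limma voom called 2.

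Within the a line at the 32-cell stage, a6.5 and a6.6 differed in 0 of 11237 genes by edgeR, with 165 genes at an unadjusted p below 0.05. With the embryo as a block 12 genes passed, 9 higher in a6.5 and 3 higher in a6.6. DESeq2 called 27 genes and limma voom called 48, and 1 gene passed without the A6.1 library of embryo 5. The unblocked fit called 26% of simulated 4-fold changes at this spread, which was estimated with the A6.1 library of embryo 5. Its count of 0 therefore does not show that a6.5 and a6.6 are alike.

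At the 64-cell stage the A-line and a-line neural-side cells A7.4 and a7.10 differed in 1244 of 11645 genes, 794 higher in A7.4 and 450 higher in a7.10. Most of these differences were moderate, with a median absolute log2 fold change of 0.998. KH.C4.341 stood at 23.0 ± 16.9 CPM in A7.4 (n = 4) and had no count in a7.10 (n = 8), at least 522-fold higher (adjusted p = 0.00341). KH.C10.399 stood at 10.8 ± 4.81 CPM in A7.4, again without a count in a7.10, at least 244-fold higher (adjusted p = 4.4e-05). In the other direction, KH.C5.586 had no count in A7.4 and 9.65 ± 5.05 CPM in a7.10, at least 159-fold higher there (adjusted p = 4.6e-05). KH.C4.624 had 1 count in A7.4 and 8.58 ± 7.07 CPM in a7.10, a ratio of 424 with a counting interval of 75.8 to 16790 (adjusted p = 0.00982). Without A7.4 embryo 5 the count was 722 genes; the highest count without 1 embryo was 1155.

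Among A-line cells of the 64-cell stage, A7.4 differed from A7.3 in 1 gene and from A7.2 in 2 genes, all higher in A7.4 in this fit. KH.S821.2 was higher than in either partner, at 7.12 ± 3.52 CPM in A7.4 against 0.0341 ± 0.0395 CPM in A7.3 and 0.109 ± 0.138 CPM in A7.2 (n = 4 each). Against the 2 counts in A7.3 the ratio was 164 with a counting interval of 45.1 to 1363 (adjusted p = 0.00788), and against A7.2 the log2 fold change was 5.73 ± 0.99 SE (adjusted p = 0.0269). With the embryo as a block the adjusted p of KH.S821.2 was 0.614 against A7.3 and 0.630 against A7.2, and the 5 genes that passed against A7.3 did not include it. It lost each call in 4 of 8 fits without 1 embryo. Other fits called genes on both sides: against A7.3, 34 higher and 9 lower in A7.4 by DESeq2, 23 and 20 by limma voom, 2 and 3 with the block and 0 and 2 in the fit of 2 groups, and against A7.2, 25 and 4 by DESeq2 and 32 and 43 by limma voom. Fits without 1 embryo gave 0 (without A7.3 embryo 2) to 8 genes (without A7.4 embryo 3) against A7.3 and 0 (without A7.2 embryo 2) to 13 genes (without A7.4 embryo 3) against A7.2.

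Among a-line cells of the 64-cell stage, a7.10 differed from the epidermis-fated a7.11 in 36 of 11645 genes, 25 higher in a7.10 and 11 higher in a7.11. KH.C11.328 stood at 40.9 ± 18.4 CPM in a7.10 (n = 8) and had no count in a7.11 (n = 6), at least 738-fold higher (log2 fold change 11.75 ± 0.69 SE, adjusted p = 1.3e-10). KH.C10.74 stood at 41.6 ± 33.6 CPM in a7.10 and 0.0942 ± 0.0845 CPM in a7.11 (adjusted p = 0.000164). KH.C12.323 had no count in a7.10 and 18.3 ± 4.18 CPM in a7.11, at least 394-fold higher there (adjusted p = 0.00720). KH.C7.157 was lower in a7.10, at 17.6 ± 16.6 against 172 ± 59.2 CPM (log2 fold change -3.29 ± 0.53 SE, adjusted p = 0.00130). With the embryo as a block over 6 paired embryos 8 genes passed, 7 of them among the 36, and KH.C12.323 was no longer past the threshold (adjusted p = 0.149). By limma voom the balance was 28 higher and 31 lower in a7.10.

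At the 112-cell stage the A-line and a-line neural-side cells A8.7 and a8.19 differed in 61 of 11334 genes, 37 higher in A8.7 and 24 higher in a8.19. KH.C8.396 stood at 16.9 ± 12.8 CPM in A8.7 (n = 5) without a count in a8.19 (n = 4), at least 325-fold higher (adjusted p = 0.0126). KH.C10.265 stood at 6.38 ± 3.71 CPM in A8.7, at least 129-fold higher (adjusted p = 0.0440). KH.S1005.1 had no count in A8.7 and 40.5 ± 38.6 CPM in a8.19, at least 766-fold higher there (adjusted p = 0.00501), or 407-fold without a8.19 embryo 2. KH.C3.862 had 1 count in A8.7 and 13.1 ± 5.04 CPM in a8.19, a ratio of 707 with a counting interval of 126 to 27970 (adjusted p = 0.00888). Fits without 1 embryo gave 33 genes (without a8.19 embryo 2) to 110 genes (without A8.7 embryo 5), and KH.C10.265 lost its call in 8 of those 9 fits and KH.C8.396 in 1.

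In the A line of 112-cell embryos, A8.7 differed from the notochord-fated A8.5 in 38 of 11334 genes, 17 higher and 21 lower in A8.7. KH.L87.38 stood at 34.7 ± 31.3 CPM in A8.7 and had no count in A8.5 (n = 5 each), at least 511-fold higher (adjusted p = 0.000380). KH.L131.13 stood at 33.1 ± 49.2 CPM in A8.7, at least 474-fold higher (adjusted p = 0.0346), and without embryo 5, which stood at 119.8 CPM, it stood at 11.4 ± 9.93 CPM, at least 180-fold higher. KH.C3.751 had 3 counts in A8.7 and 22.7 ± 8.25 CPM in A8.5, a ratio of 427 with a counting interval of 146 to 2072 (adjusted p = 0.0302). KH.L9.31 had 1 count in A8.7 and 20.04 ± 2.84 CPM in A8.5, a ratio of 1138 with a counting interval of 204 to 44990 (adjusted p = 0.0466). Blocked by embryo, 13 genes passed, 10 of them among the 38, and the adjusted p was 0.266 for KH.L87.38, 0.319 for KH.L131.13, 0.0963 for KH.C3.751 and 0.0835 for KH.L9.31. Without A8.7 embryo 3 the count was 23 genes, and of the 10 fits without 1 embryo KH.L9.31 lost its call in all 10, KH.C3.751 in 8 and KH.L131.13 in 6. By DESeq2 the balance of the genes was 114 higher and 78 lower in A8.7.

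Among a-line cells of the 112-cell stage, a8.19 differed from the epidermis-fated a8.22 in 17 of 11334 genes, 12 higher and 5 lower in a8.19. KH.C12.561 stood at 60.8 ± 26.3 CPM in a8.19 and had no count in a8.22 (n = 4 each), at least 1174-fold higher (adjusted p = 0.000262). KH.C1.697 stood at 30.2 ± 25.8 CPM in a8.19, at least 614-fold higher (adjusted p = 6.1e-05), or 397-fold without a8.19 embryo 1. KH.C9.701 was lower in a8.19, at 0.103 ± 0.125 against 145 ± 85.04 CPM (adjusted p = 0.0238). KH.L116.49 stood at 299.9 ± 49.1 CPM in a8.19 and 958 ± 199 CPM in a8.22 (log2 fold change -1.68 ± 0.24 SE, adjusted p = 0.000954). Blocked by embryo, 8 genes passed, 3 higher and 5 lower in a8.19 and 7 of them among the 17, and the adjusted p was 0.0564 for KH.C12.561 and 0.135 for KH.C1.697. KH.C9.701 lost its call in 7 of 8 fits without 1 embryo.

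At the neural plate stage A9.13+A9.14 and a9.37+a9.38 differed in 13 of 11826 genes, 3 higher in A9.13+A9.14 and 10 higher in a9.37+a9.38. KH.L128.12 stood at 64.7 ± 3.34 CPM in A9.13+A9.14 (n = 2) without a count in a9.37+a9.38 (n = 3), at least 419-fold higher (adjusted p = 0.0123). KH.C4.57 stood at 445 ± 96.7 against 2.29 ± 2.74 CPM (log2 fold change 7.65 ± 0.94 SE, adjusted p = 0.0123). KH.C11.158 had 1 count in A9.13+A9.14 and 25.9 ± 11.8 CPM in a9.37+a9.38, a ratio of 830 with a counting interval of 148 to 32830 (adjusted p = 0.0202). KH.C2.577 stood at 2.60 ± 1.12 CPM in A9.13+A9.14 and 159 ± 54.0 CPM in a9.37+a9.38 (adjusted p = 0.0409). With 2 embryos in A9.13+A9.14, the count fell to 1 gene without A9.13+A9.14 embryo 1*, where none of these 4 identifiers passed. Of 5 fits without 1 embryo, KH.C2.577 lost its call in 5, KH.C11.158 in 4, and KH.L128.12 and KH.C4.57 in 1.

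Among A-line cells of the neural plate, A9.13+A9.14 differed from A9.9+A9.10 in 25 of 11826 genes, 12 higher and 13 lower in A9.13+A9.14. KH.L131.13 stood at 117 ± 18.3 CPM in A9.13+A9.14 (n = 2) and had 2 counts in A9.9+A9.10 (n = 3), a ratio of 1790 with a counting interval of 495 to 14780 (adjusted p = 0.00149). KH.C9.717 stood at 26.7 ± 17.5 CPM without a count in A9.9+A9.10, at least 375-fold higher, or 159-fold without A9.13+A9.14 embryo 2* (adjusted p = 0.00494; 0.162 with the embryo as a block). KH.C8.603 was lower in A9.13+A9.14, at 28.2 ± 7.81 against 4314 ± 3000 CPM (log2 fold change -7.25 ± 0.92 SE, adjusted p = 0.00565). KH.S391.1 was also lower, at 0.500 ± 0.242 against 82.2 ± 79.9 CPM (adjusted p = 0.0338; 0.225 with the embryo as a block). Fits without 1 embryo gave 8 genes (without A9.13+A9.14 embryo 2*) to 60 genes (without A9.9+A9.10 embryo 2*), KH.C8.603 lost its call without either A9.13+A9.14 embryo (adjusted p of 0.108 or more), and KH.S391.1 lost it in 4 of the 5 fits.

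Among a-line cells of the neural plate, a9.37+a9.38 differed from the epidermis-fated a9.43+a9.44 in 91 of 11826 genes, 37 higher and 54 lower in a9.37+a9.38 (n = 3 each). KH.L141.7 stood at 39.4 ± 36.3 CPM in a9.37+a9.38 without a count in a9.43+a9.44, at least 543-fold higher (adjusted p = 0.0376), or 224-fold without a9.37+a9.38 embryo 1. KH.C12.562 stood at 35.5 ± 17.4 CPM, at least 447-fold higher (adjusted p = 0.0183). KH.C5.83 had no count in a9.37+a9.38 and 71.6 ± 41.9 CPM in a9.43+a9.44, at least 521-fold higher there (adjusted p = 0.0169), or 295-fold without a9.43+a9.44 embryo 1. KH.C5.21 also had no count in a9.37+a9.38 and stood at 20.2 ± 14.1 CPM in a9.43+a9.44, at least 114-fold higher (adjusted p = 0.0392; 0.160 with the embryo as a block). Without 1 embryo, 37 genes (without a9.37+a9.38 embryo 1) to 53 genes (without a9.37+a9.38 embryo 3) passed, and of these 6 fits KH.L141.7 and KH.C5.21 lost their calls in all 6 and KH.C12.562 and KH.C5.83 in 4 each.

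Genes that moved the same way from partner to neural side in both lineages were called by edgeR, with all embryos and embryo sums, at the neural plate stage. There, 5 genes were shared, 3 higher and 2 lower on both neural sides, against 0.0375 and 0.0594 expected of independent lists (one-sided Fisher's exact test, p = 6.1e-06 and 0.00155). KH.C7.140 stood at 1503 ± 190 CPM in A9.13+A9.14 and 1031 ± 406 CPM in a9.37+a9.38, against 21.98 ± 5.64 and 7.04 ± 2.58 CPM in their partners (adjusted p = 4.9e-05 and 1.1e-05). KH.C6.128 stood at 492 ± 56.2 and 661 ± 225 CPM on the neural sides and at 99.6 ± 50.5 and 109.5 ± 3.13 CPM in the partners (adjusted p = 0.0260 and 0.00465). KH.C8.603 was lower on both neural sides, at 28.2 ± 7.81 and 2.31 ± 3.04 CPM against 4314 ± 3000 and 551 ± 14.6 CPM, and so was KH.C9.700, at 15.8 ± 0.655 and 31.8 ± 12.0 CPM against 215 ± 79.2 and 414 ± 111 CPM. At 32, 64 and 112 cells 0 genes were shared in this fit. Single libraries as replicates gave 1, 0 and 5 genes, DESeq2 gave 1, 2 and 13 and limma voom gave 0, 0 and 9. At an unadjusted p below 0.05 by edgeR in both lineages, 16, 38 and 66 genes moved the same way. Another 9, 62 and 76 moved in opposite ways. Independent lists would give 30.2, 42.5 and 49.55 genes of both kinds together. The 25 genes at 32 cells were fewer than that, and the A-line list there included the A6.1 library that stood apart. At the neural plate stage 63 genes moved the same way at that level and 89 in opposite ways, where independent lists would give 48.9. DESeq2 called 20 shared and 27 opposite genes there. From 64 cells on the unadjusted lists thus overlapped more than independent lists (100, 142 and 152 genes), with more opposite than same-direction genes. The Fisher p-values take genes as independent and equally detectable, so they do not by themselves show a shared neural-side change. The 5 shared genes became 1 without A9.13+A9.14 embryo 1* and 8 without A9.9+A9.10 embryo 2*.

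Other genes moved in opposite directions in the 2 lineages. At 112 cells 6 genes did so by edgeR, against 0.0297 expected of independent lists, 4 of them higher in A8.7 than A8.5 and lower in a8.19 than a8.22. KH.L116.49 rose from 34.4 ± 10.98 CPM in A8.5 to 280 ± 74 CPM in A8.7 (adjusted p = 2.7e-07), and fell from 958 ± 199 CPM in a8.22 to 299.9 ± 49.1 CPM in a8.19. KH.C4.226 stood at 199.8 ± 33.4 CPM in A8.5, 674 ± 145 CPM in A8.7, 749 ± 151 CPM in a8.19 and 1963 ± 236 CPM in a8.22 (adjusted p = 2.7e-06 in the A line and 0.000248 in the a line). In both genes the 2 neural-side cells differed by less than 1 SE (log2 A8.7 minus a8.19 of -0.10 ± 0.22 and -0.15 ± 0.16). The reverse held for KH.C12.561, at 104 ± 42.2 CPM in A8.5, 1.27 ± 1.32 CPM in A8.7, 60.8 ± 26.3 CPM in a8.19 and no count in a8.22, and for KH.C1.697, at 125 ± 38.8, 10.0 ± 7.27, 30.2 ± 25.8 and 0 CPM in the same order. With one-sided Fisher's exact tests, p was 1.7e-11 for the first kind and 0.000213 for the second. These p-values carry the same limit as those of the shared genes, since the unadjusted lists overlapped more than independent lists. With the embryo as a block 4 genes moved in opposite ways, and both genes of the second kind lost their a-line call (adjusted p = 0.0564 for KH.C12.561 and 0.135 for KH.C1.697). At the neural plate stage 1 gene, KH.L61.10, moved in opposite ways by edgeR, against 0.0955 expected. Its log2 change from partner to neural side was 3.76 ± 0.47 SE in the A line and -2.41 ± 0.42 SE in the a line (adjusted p = 0.00537 and 0.0213).

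**Figure D3:**
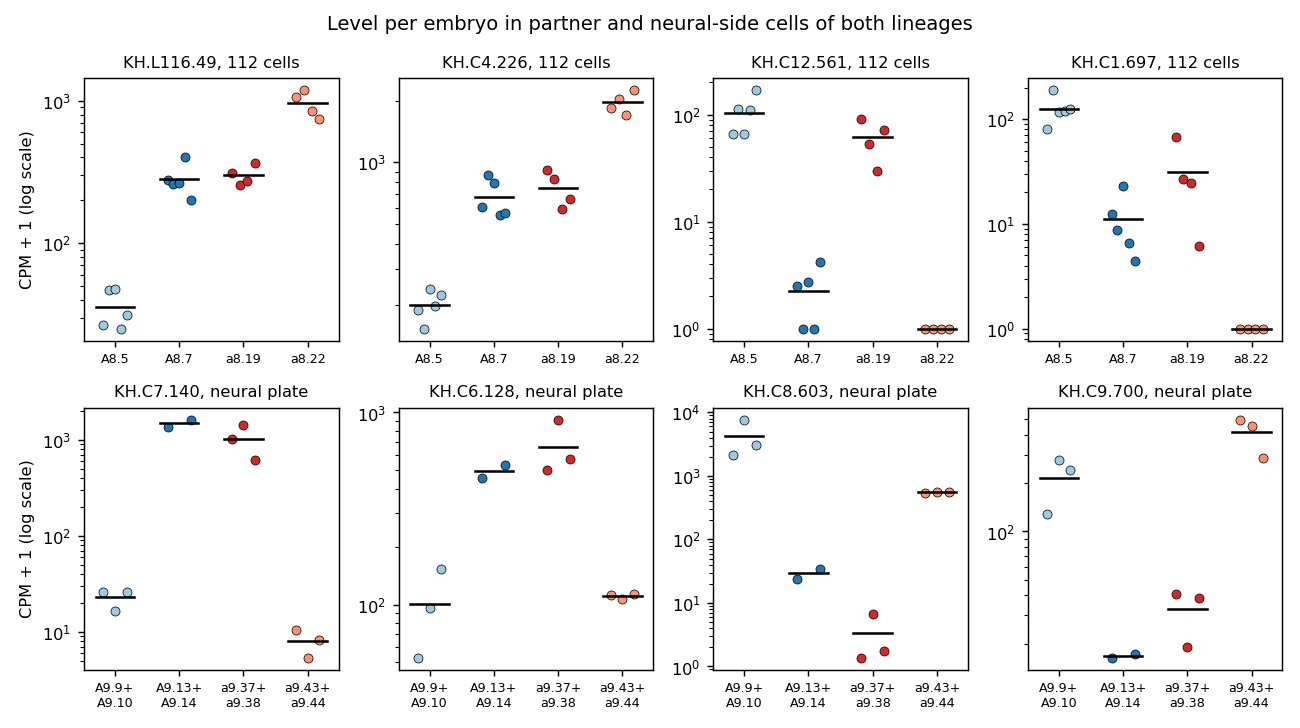
CPM plus 1 on a log scale in each embryo (points) with group means (bars), in partner and neural-side cells of both lineages, for 4 genes at 112 cells (top row) and 4 at the neural plate stage (bottom row). KH.L116.49 and KH.C4.226 have like levels in A8.7 and a8.19, between those of A8.5 and a8.22, and KH.C7.140 lies far above both partners in both neural-side cell types.

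Tested directly, the change from partner to neural side differed between the lineages in 0 genes at 32 cells, 24 at 64 cells, 46 at 112 cells and 56 at the neural plate stage. At 64 cells 5 of the differences were positive (a higher log2 change in the A line) and 19 negative, at 112 cells 19 and 27, and at the neural plate stage 32 and 24. KH.C11.328 had the log2 difference of -14.06 ± 0.89 SE at 64 cells (adjusted p = 6.8e-10), and KH.L116.49 had 4.70 ± 0.33 SE at 112 cells (adjusted p = 8.4e-08). At 32 cells 1638 genes had an unadjusted p below 0.05 by edgeR, DESeq2 and limma voom each called 14, and 2 passed without the A6.1 library of embryo 5. With embryos as blocks the counts were 4 at 32 cells and 27 at 112 cells. DESeq2 called 130, 231 and 240 genes at the 3 later stages and limma voom 77, 146 and 277. At 64 cells these were balanced, with 65 positive and 65 negative by DESeq2 and 37 and 40 by limma voom. Without 1 embryo the counts were 13 (without A7.3 embryo 4) to 44 (A7.4 embryo 3) at 64 cells, 31 (a8.19 embryo 3) to 78 (A8.7 embryo 5) at 112 cells, and 19 (A9.13+A9.14 embryo 2*) to 88 (A9.9+A9.10 embryo 2*), with 31 without a9.37+a9.38 embryo 1, at the neural plate stage. Across all tested genes, the log2 changes in the 2 lineages had a Pearson correlation of 0.0401 at 32 cells, -0.0734 at 64 cells, -0.0442 at 112 cells and -0.0517 at the neural plate stage, and a Spearman correlation of 0.122, 0.00990, -0.0311 and -0.0569; genes are not independent replicates.

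Along the neural side of each lineage, expression changed at every step between stages. In the A line, 1776 genes changed from A5.1 to A6.2 (954 of them up), 618 from A6.2 to A7.4 (349 up, 269 down), 594 from A7.4 to A8.7 (227 up, 367 down) and 930 from A8.7 to A9.13+A9.14 (432 up, 498 down). In the a line, 212 genes changed from a5.3 to a6.5 (169 up, 43 down), 1874 from a6.5 to a7.10 (773 up, 1101 down), 2476 from a7.10 to a8.19 (1267 up, 1209 down) and 2374 from a8.19 to a9.37+a9.38 (1158 up, 1216 down). KH.C7.140, shared at the neural plate stage, had no count in A6.2 and 352 ± 251 CPM in A7.4, a rise of at least 7296-fold over pooled counts (adjusted p = 0.00143), although A7.4 of embryo 3 had 1 count (0.0805 CPM) and the other 3 embryos 394 to 597 CPM. KH.C11.328 had no count in a5.3 and 30.9 ± 12.2 CPM in a6.5, at least 637-fold higher (adjusted p = 5.0e-09). KH.S567.5 fell from 46.6 ± 28.2 CPM in A7.4 to no count in A8.7 and stood at 172 ± 6.55 CPM in A9.13+A9.14 (adjusted p = 0.000660 and 0.000102). KH.S1005.1 fell to no count in both lineages, from 20.5 ± 13.7 CPM in A7.4 to A8.7 and from 41.3 ± 39.3 CPM in a8.19 to a9.37+a9.38 (adjusted p = 0.00151 and 0.00661). The balance of up and down depended on the fit: limma voom gave 982 up and 1181 down from A5.1 to A6.2, 941 and 604 from A8.7 to A9.13+A9.14, 1316 and 1973 from a7.10 to a8.19, and 1412 and 835 from a8.19 to a9.37+a9.38. In fits of 2 groups it was 215 up and 224 down from A6.2 to A7.4 and 51 and 36 from A7.4 to A8.7. Stages came from different embryos throughout, so stage and collection cannot be separated, and single embryos moved some counts. From A6.2 to A7.4 it was 408 without A6.2 embryo 1 and 342, 367 and 308 without A7.4 embryos 3, 4 and 5, and from A7.4 to A8.7 it was 346 and 327 without A7.4 embryos 4 and 5. From A8.7 to A9.13+A9.14 it was 294 and 204 without A9.13+A9.14 embryos 1* and 2* (174 in the fit of 2 groups), and from a5.3 to a6.5 it was 135 and 126 without a5.3 embryos 4 and 6 and 136 without a6.5 embryo 3.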

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

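Both tests of RNA carried over between A8.7 and a8.19, the test of library noise, the splits that keep the pairs and the repeat among genes of higher level were chosen only after the results were seen.

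A value far from the rest of its group was found in 18 of 117 groups of values, 7 among 57 groups of library measures and 11 among 60 groups of gene levels, where chance gives about 1 in 20 groups. That rate does not hold for 5 of the 11, in which all other embryos had no count, so that any count stands apart. The A6.1 library of embryo 5 (left) had 7137 genes, against 10675 to 11653 in the others, and a median r of 0.286 with its group. In that embryo KH.S215.4 stood at 52230 CPM (18.4 to 54.0 in the other A6.1 embryos) and KH.C5.217 at 99090 CPM (69.8 to 84.8), scaled by a TMM factor of 0.0375 (1957 and 3712 CPM without it). Total counts stood apart in a5.3 of embryo 6, right (14413981, others 6287481 to 9550372), in A6.2 of embryo 5, left (3451763, others 6272725 to 7713494), in A9.9+A9.10 of embryo 1*, left column 2 (16599891, others 1452103 to 6758090), and in a9.43+a9.44 of embryo 2, left column 1 (1815977, others 6232890 to 7420817). The a5.3 library of embryo 3, right, had 10606 genes (others 11421 to 11613).

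Single embryos stood apart for 9 more gene levels. KH.L131.13 was at 119.8 CPM in A8.7 of embryo 5 (others 4.42 to 25.8), KH.C7.157 at 57.0 CPM in a7.10 of embryo 6 (others 8.04 to 20.7) and KH.C9.218 at 25.9 CPM in a6.5 of embryo 3 (others 7.45 to 11.9). The other 6 were in the group with the lower level: KH.C9.541 in A5.1 of embryo 5 (0.729 CPM), KH.C9.218 in A6.2 of embryo 5 (0.247 CPM), KH.C4.624 in A7.4 of embryo 3 (0.0827 CPM), KH.L9.31 in A8.7 of embryo 5 (0.114 CPM), and KH.C3.751 and KH.C3.862 in A8.7 of embryo 7 (0.1895 and 0.0632 CPM).

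The change from partner to neural side differed between the lineages, tested in edgeR, in 24 genes at 64 cells, 46 at 112 cells and 56 at the neural plate stage. The log2 A-line change minus the a-line change is given with its SE, and where a group had no count it depends on the prior count and is no bound. At 64 cells it was 6.85 ± 1.21 for KH.S821.2, -14.06 ± 0.89 for KH.C11.328 and -8.88 ± 1.58 for KH.C10.74 (adjusted p = 0.00465, 6.8e-10 and 0.00465). At 112 cells it was 11.64 ± 1.61 for KH.L87.38, -11.24 ± 2.36 for KH.C3.751, -18.86 ± 1.73 for KH.C12.561 and -15.19 ± 1.32 for KH.C1.697 (adjusted p = 0.00185, 0.0499, 1.2e-05 and 6.8e-06). It was 19.75 ± 2.65 for KH.C9.701, 4.70 ± 0.33 for KH.L116.49 and 3.15 ± 0.24 for KH.C4.226 (adjusted p = 0.00137, 8.4e-08 and 1.7e-07). At the neural plate stage it was 13.00 ± 1.29 for KH.C9.717, 10.91 ± 1.21 for KH.L131.13, -7.31 ± 1.39 for KH.S391.1 and 18.87 ± 2.60 for KH.C5.21 (adjusted p = 0.00292, 0.00268, 0.0437 and 0.0120).

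A7.4 and a7.10 differed in 1244 genes, against 53 between A6.2 and a6.5 (1135 without the A6.1 library of embryo 5) and 61 between A8.7 and a8.19. Simulated 2-fold changes were called in 51% of genes at 64 cells and in 23% at 112 cells. The distances of 0.820 ± 0.171 and 0.660 ± 0.209 (jackknife SE) at these stages overlapped. The counts thus do not by themselves show a peak at 64 cells. A difference between lineages that persists is argued against as the whole cause of the difference at 64 cells. The A-line minus a-line difference at 64 cells had a covariance across genes of 0.0377 ± 0.0431 (jackknife SE) with that at 32 cells. With that at 112 cells the covariance was 0.187 ± 0.0556, beside 0.704 ± 0.152 with itself. A batch or handling difference of the 64-cell a-line libraries stays open, since a7.10 departed from the stages before and after by a covariance of 0.379 ± 0.0239, 0.427 above A7.4 at -0.0480 ± 0.125, and a7.11 shared this (0.392 ± 0.0225). Departures of 0.305 ± 0.0192 in a8.19 and 0.253 ± 0.0728 in A8.7 show that a7.10 is not alone in it. Stage, lineage and collection go together in the design, so such a batch and a stage-specific difference between the lineages, which was not tested, cannot be told apart.

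At 112 cells 6 genes changed in opposite directions in the lineages, 4 of them higher in A8.7 than in A8.5 and lower in a8.19 than in a8.22. Unequal depth is argued against, since with all samples thinned to 6394474 counts a median of 6 such genes passed over 5 draws (6 to 8), with all 6 genes kept in every draw. Carry-over of RNA between A8.7 and a8.19 large enough to give the graded genes their levels is argued against: it needs a share of at least 86.3%, and among 60 genes high in one of these types and low in the partner of the other the upper quartile of the share seen was 53.7% (52.6% in A8.7 and 81.3% in a8.19). A smaller carry-over stays open: genes low in the other A8.7 embryos stood in embryo 5 at a median of 27.1% of the a8.19 level (upper quartile 77.8%), against medians of 0 to 4.02% in the other embryos of both types, and without A8.7 embryo 5 the count was 7 genes. In each of the 4 graded genes A8.7 and a8.19 differed by less than 1 SE (log2 -0.153 to -0.0952). Their opposite signs thus lay in the levels of the partners A8.5 and a8.22. KH.C12.561 and KH.C1.697 differed more between A8.7 and a8.19 (log2 -5.53 ± 0.87 and -1.59 ± 0.60 SE). A biological difference between the lineages stays open too, as untested.

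Cells of 1 embryo deviated together less at later stages. Growing noise of single libraries is argued against as the whole cause, since it would leave the covariance between cells of an embryo as it was, and at 112 cells that was 23.5 ± 8.44% (SE) of its value at 32 cells. Loss of RNA that differs between embryos from the start is a candidate explanation: the 500 genes with most of this covariance at 32 cells had a median log2 change of -0.44 from 16 to 112 cells, against -0.16 in matched genes (95% of sets from -0.27 to -0.04). As low a median came up in 0 of 10000 matched sets, and likewise among genes of at least 3 log2 CPM, at -0.68 against -0.18. The matched sets drew genes independently, while the 500 genes were picked for covarying, so their spread may be too narrow. At 16 cells the covariance was 53.9 ± 43.6% (SE) of that at 32 cells, too uncertain to show a difference from the start. Collection differs between stages. At 32 cells A6.2 embryos 1 to 3 parted from embryos 4 to 6 on principal component 4 (12.27 to 17.15 against -10.57 to -3.652). Collection therefore stays open beside this.

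Other splits of the same embryos into groups of the same sizes, 100 drawn or all where fewer, were used to ask whether chance can be excluded. It can for A7.4 against a7.10 (1244 genes, highest other 88), A6.2 against a6.5 (53, 8) and a7.10 against a7.11 (36, 2). In the last of these cells are paired by embryo, and among all 64 splits that keep the pairs the highest other was 8. Cells are also paired in A8.7 against A8.5 (38, 19), a8.19 against a8.22 (17, 1) and A5.1 against a5.3 (15, 13), where the splits that keep the pairs (16, 8 and 16, with highest others of 2, 0 and 0) are too few for a share under 0.05. Chance is excluded as well for A8.7 against a8.19 (61 genes), although 1 other split gave 72, so 2 of 100 were as large. Chance can be excluded for the steps A5.1 to A6.2 (1776, 823), A6.2 to A7.4 (618, 112), A7.4 to A8.7 (594, 266), a5.3 to a6.5 (212, 158), a6.5 to a7.10 (1874, 191), a7.10 to a8.19 (2476, 189) and a8.19 to a9.37+a9.38 (2374, 1077). The same holds for the lineage difference at 64 cells (24, 18) and 112 cells (46, 1). The others among 100 splits that keep the pairs gave at most 18 and 16 there. For the 6 genes changed in opposite ways at 112 cells (6, 0) the splits cannot decide. Such a gene must be called in both lineages. Other splits of a8.19 and a8.22 called at most 1 gene, and 0 with the pairs kept, so a count near 0 was fixed in advance.

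Chance cannot be excluded for A6.2 against A6.1 (1556 genes, highest other 2864), where 12 of 100 splits gave as many, nor for A7.4 against A7.3 (1, 46; 7 of 35 splits) or A7.4 against A7.2 (2, 71; 6 of 35 splits). In the A7.4 comparisons splits with several times the real count point to a structure of the samples. On principal component 6, embryos 2 and 3 of A7.2, A7.3 and A7.4 stood at -15.81 to -9.971. Embryos 4 and 5 of these types stood at -30.96 to -25.1. The unblocked fit, which gave these counts, did not model this parting. For A6.2 against A6.1 the count was 0 without the A6.1 library of embryo 5. Among the 32, 8 and 8 splits that keep the pairs the highest others were 1541, 1 and 0. Real counts of 0 cannot exclude chance, as for a6.5 against a6.6 (highest other 10), the lineage difference at 32 cells (105), shared changes at 32, 64 and 112 cells (0 each) and opposite changes at 32 and 64 cells (0 each), where 100 of 100 splits gave as many. For a9.37+a9.38 against a9.43+a9.44 (91 genes, highest other 0), the 10 splits are too few for a share under 0.05.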

How the results depend on the processing

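The fits without the A6.1 library of embryo 5, the within-embryo distances and the embryo correlations on strictly filtered genes were tests chosen only after the data were seen. None of the 44 named identifier comparisons reversed its direction. The naming rule required every embryo of 1 group above every embryo of the other, so a reversal was unlikely from the start. The side with more genes was another than in the report in 49 of 585 alternative counts, 21 of them without 1 embryo and 28 with other choices, such as 114 higher and 78 lower in A8.7 than A8.5 with DESeq2, 3 and 1 in A6.2 against A6.1 with the embryo block and 203 and 119 in A9.13+A9.14 against A9.9+A9.10 with voom. Of 667 alternative values of results that answer a comparison, 488 stayed within 1.5 times the reported count or kept their value, 104 were higher and 75 lower. Of 749 alternative values of single identifiers, 596 kept their side of the threshold and 153 lost it. Counts of genes changed in opposite ways were higher in 19, lower in 4 and unmoved in 79 alternative values, and at 112 cells the count of 6 was 18 with DESeq2, 17 with voom and 4 with the embryo block. Of 193 alternative values of single distances, 24 moved by more than their SE or had none. All 102 alternative Pearson correlations of log2 changes stayed within a fixed tolerance of the reported ones. That tolerance was larger than each reported Pearson correlation, so a change of sign also counted as unmoved. The neural-side cells of the lineages were farther from each other than from their partners at 3 stages with a prior count of 0.5, the strict filter, RLE size factors, single libraries, and in all 77 fits without 1 embryo. Among the 77, those without an A7.2 or A9.13+A9.14 embryo could not change this. A7.2 entered none of the distances compared here, and without an A9.13+A9.14 embryo the reported distance was kept. The values below are counts of genes past the threshold. Except for fits with fewer samples or genes, the cause was not tested.

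DESeq2 called 270 for A5.1 against a5.3, 1013 for A6.2 against a6.5, 21 for A6.2 against A6.1, 27 for a6.5 against a6.6, 43 for A7.4 against A7.3 and 29 for A7.4 against A7.2. It also called 170 for a7.10 against a7.11, 388 for A8.7 against a8.19, 192 for A8.7 against A8.5, 155 for a8.19 against a8.22, 108 for A9.13+A9.14 against a9.37+a9.38 and 155 for A9.13+A9.14 against A9.9+A9.10. Further DESeq2 counts were 273 for a9.37+a9.38 against a9.43+a9.44, 1168 for A7.4 against A6.2, 1125 for A8.7 against A7.4, 1483 for A9.13+A9.14 against A8.7, 469 for a6.5 against a5.3 and 231 for the lineage difference at 112 cells. The last of these were 14 for the lineage difference at 32 cells, 240 for the lineage difference at the neural plate stage, 130 for the lineage difference at 64 cells, 13 for shared changes at 112 cells, 1 for shared changes at 32 cells and 20 for shared changes at the neural plate stage. It also called 2 for shared changes at 64 cells.

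Limma voom with an estimated embryo correlation called 9 for A5.1 against a5.3, 495 for A6.2 against a6.5, 2 for A6.2 against A6.1, 48 for a6.5 against a6.6, 43 for A7.4 against A7.3 and 75 for A7.4 against A7.2. Voom also called 59 for a7.10 against a7.11, 344 for A8.7 against a8.19, 106 for A8.7 against A8.5, 155 for a8.19 against a8.22, 141 for A9.13+A9.14 against a9.37+a9.38 and 322 for A9.13+A9.14 against A9.9+A9.10. Further voom counts were 341 for a9.37+a9.38 against a9.43+a9.44, 972 for A7.4 against A6.2, 1179 for A8.7 against A7.4, 1545 for A9.13+A9.14 against A8.7, 447 for a6.5 against a5.3 and 146 for the lineage difference at 112 cells. For shared or remaining results it called 14 for the lineage difference at 32 cells, 277 for the lineage difference at the neural plate stage, 77 for the lineage difference at 64 cells, 9 for shared changes at 112 cells and 24 for shared changes at the neural plate stage.

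Single libraries as replicates, which treats cells of 1 embryo as independent, gave 43 for A5.1 against a5.3, 333 for A6.2 against a6.5, 4 for a6.5 against a6.6, 9 for A7.4 against A7.3, 4 for A7.4 against A7.2 and 217 for A8.7 against a8.19. This choice also gave 60 for A8.7 against A8.5, 66 for a8.19 against a8.22, 130 for A9.13+A9.14 against a9.37+a9.38, 153 for A9.13+A9.14 against A9.9+A9.10, 267 for a9.37+a9.38 against a9.43+a9.44 and 1563 for A7.4 against A6.2. Further such counts were 1164 for A8.7 against A7.4, 2473 for A9.13+A9.14 against A8.7, 320 for a6.5 against a5.3, 109 for the lineage difference at 112 cells, 664 for the lineage difference at 32 cells and 240 for the lineage difference at the neural plate stage. The remaining such counts were 54 for the lineage difference at 64 cells, 5 for shared changes at 112 cells, 1 for shared changes at 32 cells and 22 for shared changes at the neural plate stage. Fits of only the 2 groups compared, with fewer samples behind the spread, gave 1129 for A6.2 against a6.5, 0 for A6.2 against A6.1, 4 for a6.5 against a6.6, 2 for A7.4 against A7.3, 0 for A7.4 against A7.2 and 42 for a8.19 against a8.22. These smaller fits also gave 48 for A9.13+A9.14 against a9.37+a9.38, 3 for A9.13+A9.14 against A9.9+A9.10, 152 for a9.37+a9.38 against a9.43+a9.44, 2737 for A6.2 against A5.1, 87 for A8.7 against A7.4 and 174 for A9.13+A9.14 against A8.7. The others were 483 for a6.5 against a5.3, 1635 for a8.19 against a7.10 and 1251 for a9.37+a9.38 against a8.19.

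The strict filter gave 37 for A5.1 against a5.3. Without the low-count filter there were 5 for A5.1 against a5.3. RLE size factors gave 225 for A6.2 against a6.5. At an adjusted p below 0.1 there were 1 for shared changes at 112 cells and 10 for shared changes at the neural plate stage. Leaving out the A6.1 library of embryo 5 gave 1135 for A6.2 against a6.5, 0 for A6.2 against A6.1, 1 for a6.5 against a6.6 and 2 for the lineage difference at 32 cells.

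The embryo block, where the labels pair the cells, gave 128 for A5.1 against a5.3, 4 for A6.2 against A6.1, 12 for a6.5 against a6.6, 5 for A7.4 against A7.3 and 8 for a7.10 against a7.11. It also gave 13 for A8.7 against A8.5, 8 for a8.19 against a8.22, 27 for the lineage difference at 112 cells and 4 for the lineage difference at 32 cells. The block changed no other count by over 1.5 times: it gave 2 for A7.4 against A7.2, 29 for A9.13+A9.14 against A9.9+A9.10, 133 for a9.37+a9.38 against a9.43+a9.44, 16 and 68 for the lineage difference at 64 cells and the neural plate stage, and 0, 0, 0 and 6 shared changes at the 4 stages. The embryo numbers of A-line and a-line cells at 32, 64 and 112 cells were not shown to pair them: among 5, 4 and 2 shared numbers, 2, 0 and 2 A-line samples correlated best with the a-line sample of their own number. A block on these numbers gave 699 for A6.2 against a6.5, 206 for A7.4 against a7.10 and 12 for A8.7 against a8.19. No paired analysis was possible for A9.13+A9.14 against a9.37+a9.38 because their embryos carry different marks, nor between stages, which come from different embryos.

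Without 1 embryo at a time, the counts ranged from 2 to 24 for A5.1 against a5.3, 25 to 42 for A6.2 against a6.5, 0 to 1724 for A6.2 against A6.1, 0 to 0 for a6.5 against a6.6, 722 to 1155 for A7.4 against a7.10 and 0 to 8 for A7.4 against A7.3. They ranged from 0 to 13 for A7.4 against A7.2, 24 to 47 for a7.10 against a7.11, 33 to 110 for A8.7 against a8.19, 23 to 46 for A8.7 against A8.5, 13 to 19 for a8.19 against a8.22 and 1 to 12 for A9.13+A9.14 against a9.37+a9.38. Further ranges were 8 to 60 for A9.13+A9.14 against A9.9+A9.10, 37 to 53 for a9.37+a9.38 against a9.43+a9.44, 1215 to 1808 for A6.2 against A5.1, 308 to 710 for A7.4 against A6.2, 327 to 633 for A8.7 against A7.4 and 204 to 1041 for A9.13+A9.14 against A8.7. For others they ran from 126 to 274 for a6.5 against a5.3, 1482 to 1864 for a7.10 against a6.5, 2039 to 2468 for a8.19 against a7.10, 1881 to 2257 for a9.37+a9.38 against a8.19, 31 to 78 for the lineage difference at 112 cells and 0 to 2 for the lineage difference at 32 cells. The lineage differences and shared changes had 19 to 88 for the lineage difference at the neural plate stage, 13 to 44 for the lineage difference at 64 cells, 0 to 2 for shared changes at 112 cells, 0 to 0 for shared changes at 32 cells, 1 to 8 for shared changes at the neural plate stage and 0 to 0 for shared changes at 64 cells. Of the 44 named identifier comparisons, 23 lost the threshold in at least 1 such fit, 10 in fits of 2 groups, 6 with voom, 3 with DESeq2, 3 without the filter and 1 with RLE size factors, and 21 of the 40 that a block could fit lost it with the block. Without A9.13+A9.14 embryo 1* or 2*, 294 or 204 genes changed from A8.7 and 11 or 8 from A9.9+A9.10, and without a9.37+a9.38 embryo 3 the lineage difference at the neural plate stage was 52. With 1 embryo left in A9.13+A9.14, that embryo is assumed to vary like the embryos of other groups.

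Depth limits the neural plate stage most. A gene without a count over all libraries of a9.37+a9.38 can still stand at 0.161 CPM, and one without a count in the shallowest A9.9+A9.10 library at 2.07 CPM, both from 3 counts. Tests of the fixed gene lists were not run, since the identifiers carry no names.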

Other observations

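The genes below were singled out only after their values were seen, while the tests of side and column were planned.

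KH.C11.328, past the threshold in a7.10 against a7.11, had its higher mean on the neural side of the a line and on the partner side of the A line. Among a-line cells it stood at 26.5 ± 10.5 CPM in a6.5 against 0.876 ± 1.69 in a6.6, 157 ± 31.5 in a8.19 against 2.12 ± 3.38 in a8.22, and 372 ± 208 in a9.37+a9.38 against 10.9 ± 6.14 in a9.43+a9.44 (SD; n = 5, 4 and 3 embryos). By edgeR only the last of these passed (adjusted p = 0.00806), with adjusted p = 0.903 at 32 cells and 0.0824 at 112 cells. Among A-line cells it stood at 68.6 ± 10.1 CPM in A7.3 against 13.7 ± 7.35 in A7.4 (n = 4 each), and at 434 ± 359 CPM in A9.9+A9.10 (n = 3), with a log2 change to A9.13+A9.14 (n = 2) of -4.60 ± 0.88 SE, but neither passed (adjusted p = 0.0989 and 0.0746). At 32 and 112 cells the A-line means differed by less than the SD, at 20.4 ± 30.8 CPM in A6.1 (22.5 ± 33.9 without embryo 5) against 17.7 ± 9.40 in A6.2, and 49.8 ± 23.2 in A8.5 against 28.6 ± 39.0 in A8.7.

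KH.C7.140, higher on both neural sides at the neural plate stage, had another order at 64 cells. There it stood at 362 ± 259 CPM in A7.4 and 588 ± 79.8 CPM in its sister A7.3 (adjusted p by edgeR = 1), and at 22.7 ± 4.65 CPM in A7.2 (n = 4 each). At 112 cells it stood at 1440 ± 271 CPM in A8.7 against 42.7 ± 48.4 CPM in A8.5 (n = 5; log2 5.07 ± 0.61 SE, adjusted p = 0.000276). In a8.19 it was at 343 ± 112 CPM against 65.5 ± 51.3 CPM in a8.22 (n = 4; adjusted p = 0.251).

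Left and right cells of the same type and embryo differed in 0 genes by edgeR at 16, 32, 64 and 112 cells, with 322, 492, 411 and 421 genes at an unadjusted p below 0.05, where chance gives 499, 552, 513 and 546. At 64 cells the test covered A-line cells only, since all a7.10 and a7.11 libraries came from the right side. A7.4 libraries came from both sides, so side was not balanced between A7.4 and a7.10. Cells of column 1 and column 2 at the neural plate stage also differed in 0 genes by edgeR in any cell type, with 253 to 797 genes at an unadjusted p below 0.05 against 539 by chance. The 797 came from A9.9+A9.10, where the test had 4 libraries of 1 embryo, so its cells stood in for replicates. Over all cell types together (7 pairs of embryo and type, 20 libraries) 0 genes differed between the columns, with 333 at an unadjusted p below 0.05. No other tool was run on these, and the power of these tests was not measured, so they do not show that there is no difference.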
